A study of Mus musculus with 5 samples.

How the data were processed

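RNA of E14 mouse embryonic stem cells was measured on 5 arrays. The cells were kept on mouse embryo fibroblast feeder cells. Per the labels' protocols, the medium held 14% serum replacement, 1% fetal bovine serum and 100 units/ml of leukaemia inhibitory factor, and biotin-labelled RNA was made from 6 µg of total RNA for hybridisation to Affymetrix arrays. Per the labels, 2 samples were wild type (WT) and 3 were homozygous for a Trip12 mutation (Trip12 mut/mut), each named a biological replicate; how the replicates were made is not given in the sources used here. What the mutation is, and whether feeder cells were removed before the RNA was extracted, is not given in the sources used here.

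The deposited values are on the log2 scale, 1 value per probe set and array. Per the submitters' processing notes they were made with RMA, a method that corrects background, normalises arrays to each other and summarises the probes of a probe set. Its version is not given in the sources used here, and scanner files were not used here. The array medians over all probe sets without controls lay between 5.51 and 5.55, so a shift shared by all transcripts could not be measured. RMA gives no detection call, and many dim probe sets had the same value on several arrays, which makes the spread of those probe sets 0 and lowers the precision of a test that shares variances. The number of arrays limits the precision of every value.

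Of 45101 probe sets, 64 were array controls and were left out of the tests, which leaves 45037. The platform annotation gave 34945 of these 1 gene symbol, 932 several and 9160 none. Symbols of 34741 probe sets were updated by gene number through a table of assembly GRCm38.p6, which was used only for names, chromosomes and gene order. A gene was represented by the probe set with the highest mean over the 5 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Probe sets with several symbols named no gene.

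Genes and probe sets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all genes or probe sets tested, with a threshold of 0.05, and differences of at least 1 on the log2 scale (2-fold) were counted separately. All differences are Trip12 mut/mut minus WT. There were 34 gene lists with 777 genes, of which 698 were measured. They were tested with limma's camera at a preset inter-gene correlation of 0.01 for lists with at least 5 members, and adjusted over lists. The genes of each chromosome were tested the same way. So were the 25 genes on each side of Trip12, as a single list whose p-value was not adjusted. The groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined.

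The naming rule took the 12 genes with the largest positive and the 12 with the largest negative difference. It required a gene past the threshold, with each mutant array on the same side of both WT arrays, and with a higher group mean at or above the median of all probe sets, 5.52. Up to 4 members with the smallest adjusted p were named in each list. No gene met the first part of the rule over all 5 arrays. After the data were examined, the same rule was applied to a comparison without the array labelled Trip12 mut/mut replicate 1. That comparison was limited to genes with at least 2 of the 4 remaining arrays above that median, which left 11623 genes. There 539 genes met the rule, 523 of them with a gene name. Leaving out that array, and filtering dim probe sets, were each chosen in advance; using them together was decided after the data were examined. Because the array was set aside for its values, the p-values of that comparison are too favourable and are no independent evidence.

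Alternatives chosen in advance were quantile normalisation, centring of array medians, a filter on dim probe sets, a variance trend with robust estimation, array weights, a replicate block, each array left out, the mean of a gene's probe sets, the probe set with the largest SD, an estimated inter-gene correlation and the rotation test fry. With an estimated correlation, camera uses only the residual degrees of freedom of the few arrays. A list that does not pass there is therefore not shown to be unchanged. The procedure was tested on simulated data. With the spread of the 5 arrays over 18193 genes, it recovered 88 of 100 genes changed by 2 and 61 of 100 genes changed by 1 on the log2 scale, with 12 false calls. With the spread of the 4 arrays over 11623 genes, it recovered 79 of 100 and 50 of 100, with 3 false calls. The simulated changes were placed on every mutant array, in genes drawn at random. These rates therefore do not apply to changes carried by only some mutant arrays, which widen a gene's own spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.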

Results

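Transcript levels were measured on 5 Affymetrix arrays, 2 from WT and 3 from Trip12 mut/mut embryonic stem cells. Trip12 encodes a HECT-type E3 ubiquitin ligase, an enzyme that attaches ubiquitin to target proteins. The series concerns a Trip12 mutation in an embryonic stem cell line, and its single comparison is mutant against WT. Values are log2 RMA values.

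The Trip12 probe set with the highest signal read 10.21 ± 0.06 (SD, n = 2) in WT cells. It read 10.18 on the array labelled Trip12 mut/mut replicate 1, 12.09 on replicate 2 and 12.57 on replicate 3. Relative to the WT mean these are 0.98-fold, 3.69-fold and 5.13-fold. The mutant mean of 11.62 ± 1.26 (SD, n = 3) was 1.41 above WT with an SE of 0.79, and this difference did not pass the test over all probe sets (limma, adjusted p = 0.784). Without the array labelled replicate 1 the difference was 2.12, a 4.35-fold higher signal, with an adjusted p of 0.116 over all probe sets, and 0.0595 with dim probe sets removed. In the filtered comparison over genes its adjusted p was 0.0421.

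The Trip12 probe sets did not all move one way. Of the other 6, the one with a WT mean of 8.01 was at 2.17-fold the WT mean on both replicates 2 and 3. The one with a WT mean of 6.68 was at 2.03-fold and 2.05-fold, and the one at 6.67 was at 1.41-fold and 1.84-fold. In contrast, the one with a WT mean of 6.10 was at 0.751-fold and 0.551-fold. On the array labelled replicate 1 these 4 probe sets lay between 0.978-fold and 1.07-fold of WT. The remaining 2 were dim, with WT means of 3.77 and 3.05. Where these probe sets lie relative to the mutation is not given in the sources used here, so the signal does not report the amount of functional transcript.

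**Figure D1:**
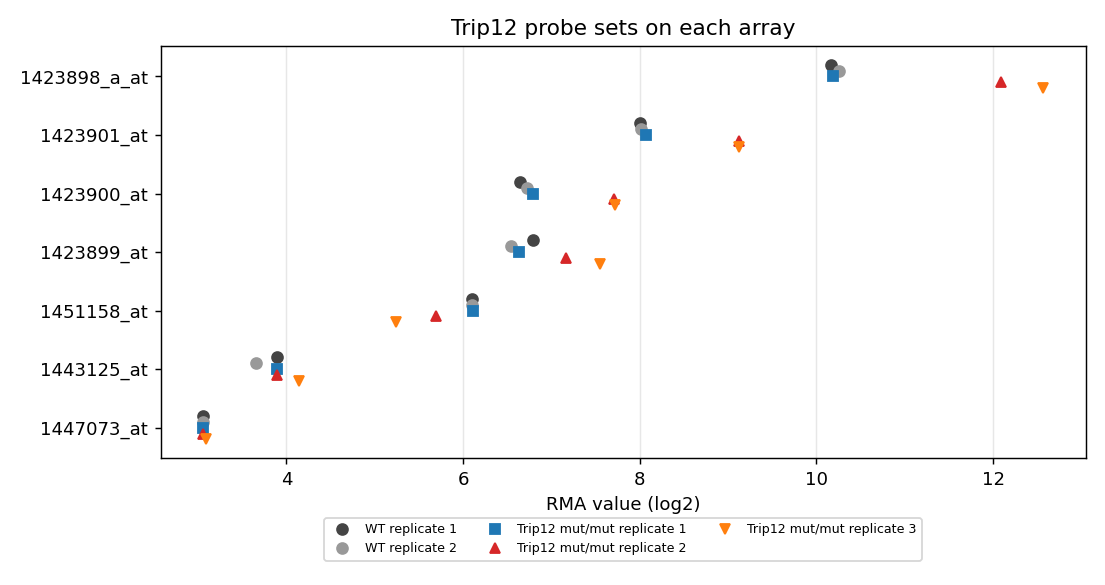
Log2 RMA values (horizontal axis) of the 7 Trip12 probe sets (vertical axis) on each of the 5 arrays; each point is 1 array, offset vertically for legibility. For the 5 brighter probe sets the array labelled Trip12 mut/mut replicate 1 lies with the 2 WT arrays, and replicates 2 and 3 lie apart, at 12.09 and 12.57 for the probe set at the top. For the 2 dim ones replicate 2 lies with the WT arrays.

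The array labelled Trip12 mut/mut replicate 1 was as close to each WT array as these were to each other. Across 45037 probe sets, the 2 WT arrays correlated at r = 0.9989 with an SD of differences of 0.123. The array labelled replicate 1 correlated with them at 0.9989 and 0.9988, with SDs of 0.123 and 0.124, and 0 probe sets differed by more than 2-fold in any of these pairs. Replicate 2 differed from WT by more than 2-fold at 475 and 545 probe sets, and replicate 3 at 293 and 297. Replicates 2 and 3 differed from each other at 9. These correlations are across probe sets, which are not independent replicates. The direction of the named genes, and of the 12 gene lists that passed over all 5 arrays, therefore rests on replicates 2 and 3. The labels name the 3 like arrays biological replicates, and the values do not settle whether they came from separate cultures or from 1 RNA. In the latter case the WT SD would measure technical spread only, and the SEs and p-values below, which also draw on the spread between replicates 2 and 3, would rest in part on it.

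**Figure D2:**
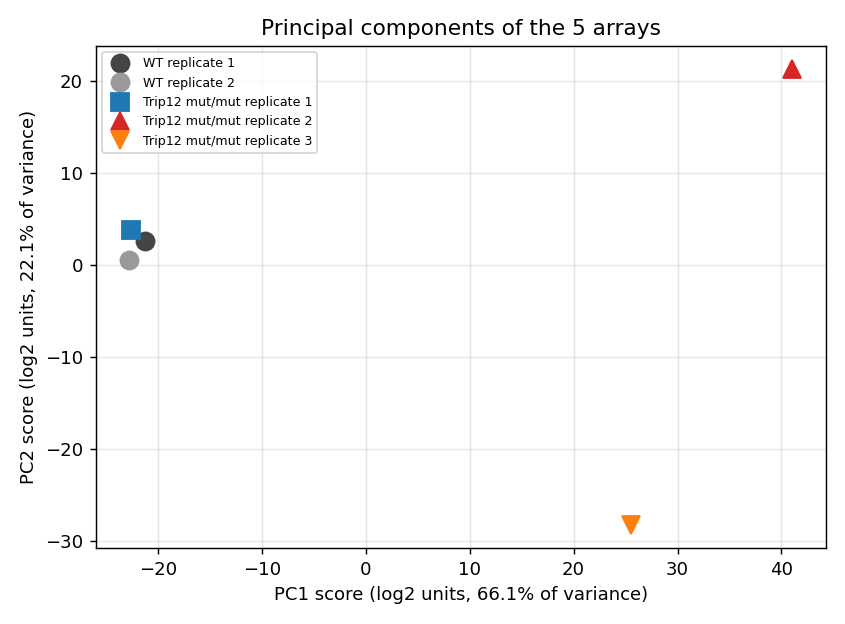
Scores of the 5 arrays on the first principal component (horizontal axis, log2 units, 66.1% of the variance) and the second (vertical axis, log2 units, 22.1%); each point is 1 array. The array labelled Trip12 mut/mut replicate 1 has a PC1 score of -22.6, beside the WT arrays at -21.2 and -22.8, and replicates 2 and 3 are at 41.0 and 25.5.

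Over all 5 arrays as labelled, 0 of 18193 genes passed the threshold in limma, and 0 were called at 2-fold or more. An unadjusted p below 0.05 was found for 214 genes, where 910 would be expected by chance, and the smallest adjusted p was 0.748. Of 45037 probe sets 0 passed, with 658 below an unadjusted 0.05. The 2 groups did not overlap for 2187 genes, or 12% of all genes, where chance gives at most 20%. Tied values cannot count as separate, and many dim probe sets had them, so a shortfall from 20% cannot be read. Without the array labelled replicate 1 again 0 genes passed, with 3730 below an unadjusted 0.05 and a smallest adjusted p of 0.0785. With dim probe sets removed as well, 539 of 11623 genes passed, 383 higher and 156 lower, and 124 differed by at least 2-fold, 50 higher and 74 lower. The corresponding comparison over probe sets called 15, of which 1 was higher.

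The genes with the largest decreases on replicates 2 and 3 included regulators and markers of the early epiblast. In that filtered comparison without the array labelled replicate 1, Nefm, a neurofilament subunit, fell by 3.04 on the log2 scale (SE 0.11, adjusted p = 0.0243), and was 8.20-fold lower. Fgf5, a growth factor gene of the postimplantation epiblast, was lower by a factor of 7.23 (adjusted p = 0.0454). Otx2, a transcription factor of the epiblast and anterior neural plate, read 10.24 ± 0.02 (SD, n = 2) in WT, 10.18 on the array labelled replicate 1, and 7.80 and 7.79 on replicates 2 and 3. It was lower by a factor of 5.46 (adjusted p = 0.0243). The tight junction gene Cldn7 was lower by a factor of 5.09, the splicing regulator of epithelial cells Esrp1 by 4.22, and the carbonic anhydrase genes Car4 and Car3 by 4.98 and 4.20. Dppa3, a maternal and germline factor, was lower by 4.30, the kinase gene Pim2 by 4.4, the transcription factor gene Myb by 4.47, Irs4 by 4.61 and Fndc3c1 by 5.15. As labelled, over all 5 arrays, the adjusted p of each of these 12 genes was 0.748.

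Among the genes with the largest increases in the same comparison, Trip12 came first. Sprr2h, of a family of cornified envelope proteins, was 3.67-fold higher (log2 difference 1.88, SE 0.09, adjusted p = 0.0341). Lce1f, of another such family, was 2.53-fold higher. Mras, a small GTPase gene, was 3.29-fold higher, Ankrd1 3.18-fold, Mmrn2 3.17-fold, the arginine methyltransferase gene Prmt8 3.05-fold and the prolactin family gene Prl8a9 2.94-fold. U90926 was 2.75-fold higher, Calcoco2, an autophagy receptor gene, 2.54-fold, the germ cell gene Dazl 2.51-fold, and Timp3, an inhibitor of metalloproteinases, 2.42-fold. As labelled, over all 5 arrays, each had an adjusted p of 0.748. Of the 539 genes, 183 had another probe set above the median, and for 14 of them such a probe set had the opposite sign.

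**Figure D3:**
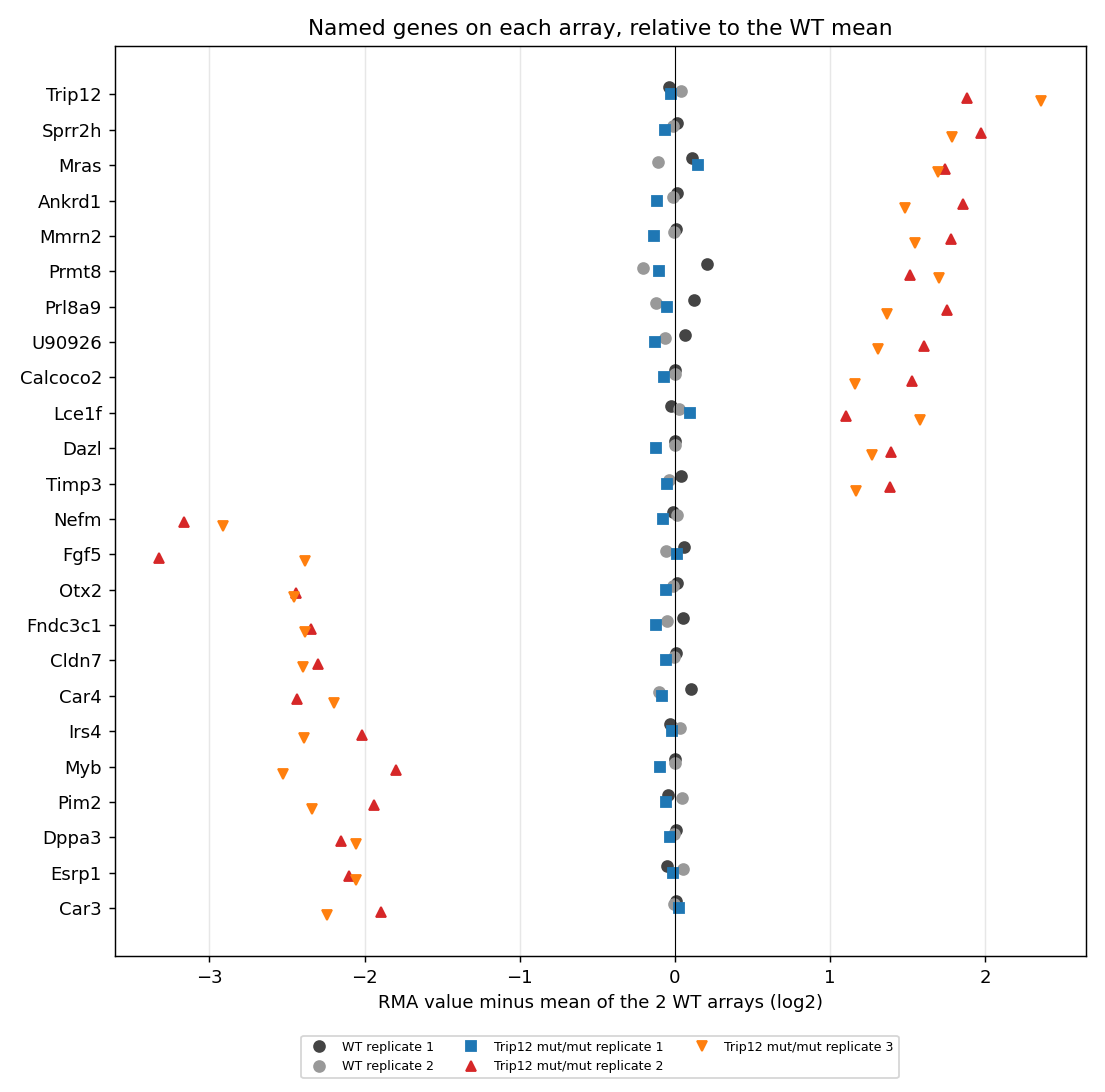
Log2 RMA value minus the mean of the 2 WT arrays (horizontal axis) for the 24 named genes (vertical axis); each point is 1 array. The genes were chosen without the array labelled Trip12 mut/mut replicate 1, which lies near 0 for each of them; replicates 2 and 3 lie apart from it in the same direction.

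Genes of the primed epiblast, the pluripotent state that follows implantation, were lower on replicates 2 and 3, beside higher fibroblast genes on both. The mean of the 17 measured members was 9.21 and 9.19 on the WT arrays and 9.17 on the array labelled replicate 1, against 8.06 and 7.93 on replicates 2 and 3. Over all 5 arrays the median difference was -0.82 (camera, adjusted p = 2.31e-05; adjusted p = 0.592 with an estimated correlation). No member passed over all 5 arrays, either over all genes or adjusted over the list alone. In the filtered comparison without that array, 12 of 17 fell and 0 rose; adjusted over the list alone, 13 fell and 2 rose. Besides Otx2, the list held Lef1, a mediator of Wnt signalling (-2.06), and the de novo DNA methyltransferases Dnmt3b (-1.69) and Dnmt3a (-1.03). Dnmt3a and Dnmt3b also were the 2 of 24 polycomb and DNA methylation genes that fell, with 0 higher, and that list did not pass over all 5 arrays (median -0.04, adjusted p = 0.119). Without the array labelled replicate 1 it passed (camera, adjusted p = 0.048; adjusted p = 0.362 with an estimated correlation).

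Core and naive pluripotency genes did not pass as a list over all 5 arrays (median -0.07, camera adjusted p = 0.214). Without the array labelled replicate 1 the median was -0.10. The list then passed with fry, direction down (adjusted p = 0.0351), and did not with camera (adjusted p = 0.135). Fry asks whether members change at all, and camera whether they change more than other genes. With fry 14 of 34 lists passed there. In the filtered comparison 4 of 29 fell and 1 rose. Adjusted over the list alone, 6 fell and 5 rose. Dppa3 fell by 2.10, Lin28a by 0.97, Lefty1 by 0.94 and Utf1 by 0.80, and Tcl1 rose by 0.55. Wnt target genes were lower (median -0.15, camera adjusted p = 0.00865; adjusted p = 0.592 with an estimated correlation). The call was lost without replicate 2 (adjusted p = 0.165), and without WT replicate 1 (0.0721) or WT replicate 2 (0.0622). The median was -0.08 without replicate 3, -0.10 without WT replicate 1, -0.27 without the array labelled replicate 1, -0.34 with dim probe sets removed and -0.50 with both of the last 2. This decrease, too, stood beside the higher fibroblast genes on replicates 2 and 3. Of 11 tested in the filtered comparison 3 fell, namely Lef1, Sp5 (-1.11) and Tnfrsf19 (-0.81), and 0 rose. Targets of TGF-beta, Nodal and BMP signalling did not pass (median 0.18, adjusted p = 0.557). In the filtered comparison 2 of 18 rose, among them Id4 (0.96), and 2 fell, Lefty1 and Lefty2 (-0.70). FGF and ERK target genes had a median of -0.0008 (0.0071 without the array labelled replicate 1) and an adjusted p of 0.525, and 0 of 21 passed.

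Marker genes of fibroblasts, the cell type of the feeder layer, were higher on replicates 2 and 3. The mean of 29 members was 10.51 and 10.51 in WT, 10.48 on the array labelled replicate 1, and 10.99 and 10.96 on replicates 2 and 3. The median over all 5 arrays was 0.36 (camera, adjusted p = 9.7e-05; adjusted p = 0.592 with an estimated correlation). In the filtered comparison 9 of 29 rose and 1 fell; adjusted over the list alone, 22 rose and 1 fell. Without replicate 3 the list did not pass (camera, adjusted p = 0.0896), and without replicate 2 its median was 0.24. Timp3 rose by 1.28, Twist2, a mesenchymal transcription factor, by 0.90 and Prrx1 by 0.66, whereas Cnn1, a smooth muscle calponin, fell by 1.10. Lum and Mmp2, named after their values were seen, averaged 10.03 and 10.23 in WT, and were at 9.72 and 9.86 on replicate 2 and at 10.37 and 10.30 on replicate 3.

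Interferon response genes were also higher (median 0.20, camera adjusted p = 0.00296), as were p53 target genes (0.15, 0.00796) and genes of glycolysis and hypoxia (0.10, 0.0292). With an estimated correlation each of these 3 lists had an adjusted p of 0.592. Without replicate 2 the interferon median was 0.11 and that of glycolysis and hypoxia 0.06, and without replicate 3 that of the p53 targets was 0.10. Without replicate 3 none of the 3 passed (adjusted p = 0.154, 0.527 and 0.137), and glycolysis and hypoxia also did not pass with any other array left out except the array labelled replicate 1. It also did not pass with the mean of probe sets (adjusted p = 0.104) or the probe set with the largest SD (0.199). The p53 targets also did not pass without WT replicate 1 (0.0556) or WT replicate 2 (0.0598). Of 26 interferon genes in the filtered comparison 5 rose and 0 fell, among them the transcription factor Irf7 (0.91) and the antiviral enzyme Oas2 (1.27). Of 22 p53 targets 1 rose, Perp (0.85), and of 27 glycolysis and hypoxia genes 4 rose, among them the oxidoreductase Ero1a (1.02) and the collagen prolyl hydroxylase P4ha2 (0.78). These increases stood beside the higher fibroblast genes on the same 2 arrays. Genes of amino acid and endoplasmic reticulum stress did not pass over all 5 arrays (median 0.10, adjusted p = 0.105), but did with array weights (0.13, 0.0337). They passed without the array labelled replicate 1 (camera, adjusted p = 0.0191; adjusted p = 0.467 with an estimated correlation), and did not with dim probe sets removed as well (0.0718). In the filtered comparison 5 of 30 rose, including Atf4 (0.80) and Herpud1 (0.79), and the amino acid transporter Slc7a3 fell by 1.41.

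Genes of DNA replication in S phase were lower by a small amount (median -0.20, camera adjusted p = 2.27e-06), as were genes of G2 and M phase (-0.11, 0.00865), DNA damage repair (-0.10, 0.0123), cholesterol synthesis (-0.13, 0.00296), the proteasome (-0.06, 0.00713) and ribosomal proteins (-0.03, 0.0392). With an estimated correlation each of these 6 lists had an adjusted p of 0.592. The ribosomal protein call was also lost with quantile normalisation (median -0.015, adjusted p = 0.293) and with the filter on dim probe sets (-0.03, 0.085). The calls of G2 and M phase, DNA damage repair, the proteasome and ribosomal proteins were lost without replicate 3 (adjusted p = 0.092, 0.13, 0.0896 and 0.258), where their medians were -0.07, -0.03, -0.026 and -0.012. With the probe set with the largest SD the G2 and M phase median was -0.18. Without WT replicate 1, G2 and M phase (0.0556), DNA damage repair (0.0852) and ribosomal proteins (0.111) were lost, and without WT replicate 2 these 3 and the proteasome (each 0.0598). Of the 6 lists only S phase and cholesterol synthesis passed with each array left out in turn. These decreases stood beside the higher fibroblast genes on the same 2 arrays. Few single members passed in the filtered comparison. In the S phase list 2 of 29 fell, Chaf1b (-0.53) and Gins1 (-0.60), and Rpl14 (-0.54) was the only one of 22 ribosomal protein genes. The other 4 lists had 0. Cyclin-dependent kinase inhibitors did not pass as a list over all 5 arrays (median 0.13, adjusted p = 0.482). In the filtered comparison Cdkn2c (0.78) and Cdkn2a (0.62) rose and 0 of 8 fell. In all 12 of 34 lists passed over all 5 arrays, 4 higher and 8 lower, against 0 with an estimated correlation and 0 with fry. Without the array labelled replicate 1, 14 lists passed with fry and 0 with an estimated correlation. With the preset correlation the count was 4 without replicate 3, 6 and 5 without WT replicates 1 and 2, and 17 without the array labelled replicate 1, where the medians of the 12 lists were 1.37 to 1.74 times those over all 5 arrays.

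**Figure D4:**
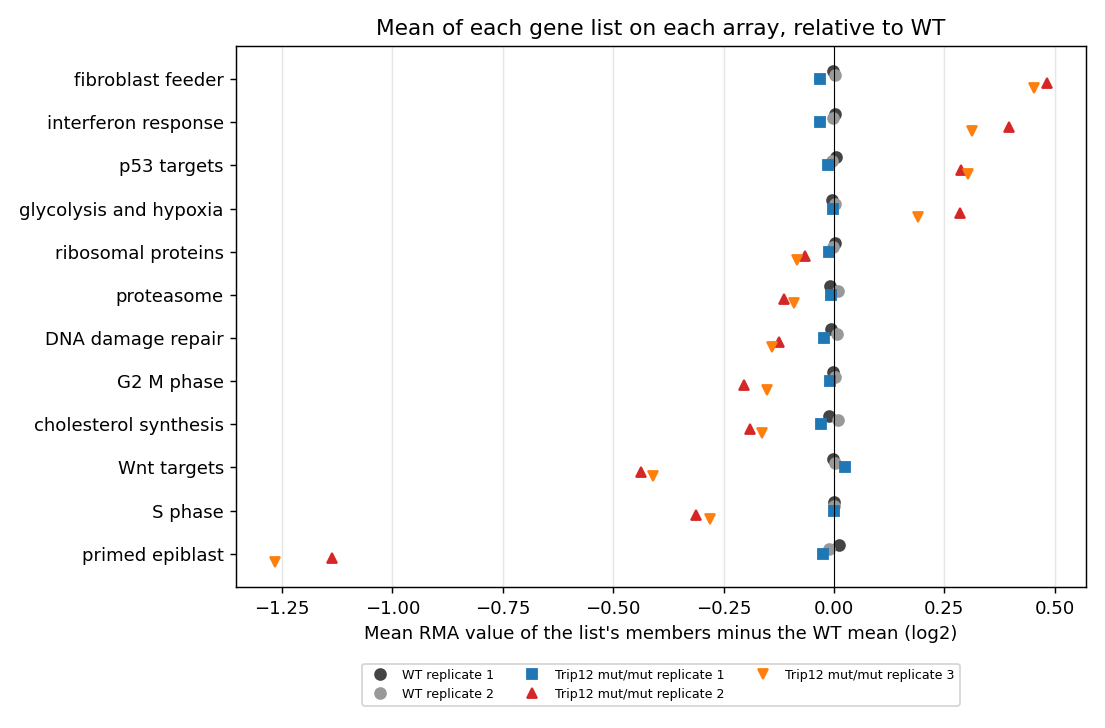
Mean log2 RMA value of the measured members minus the WT mean (horizontal axis) for the 12 gene lists past the camera threshold over all 5 arrays (vertical axis); each point is 1 array. Replicates 2 and 3 lie on the same side of WT for each list and the array labelled Trip12 mut/mut replicate 1 lies near 0; none of the 12 passed with an estimated correlation.

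Other lineage lists did not pass over all 5 arrays in the main comparison. Members said below to rise, fall or pass did so in the filtered comparison without the array labelled replicate 1. Over all 5 arrays 0 genes passed. Primitive and visceral endoderm genes had a median of 0.09 (adjusted p = 0.072). That list passed over all 5 arrays with dim probe sets removed (median 0.19, adjusted p = 0.0461) or with array weights (0.14, 0.0104), and without the array labelled replicate 1 (0.23, 0.0105; adjusted p = 0.353 with an estimated correlation). Of its members 4 of 16 rose in the filtered comparison, with the basement membrane genes Col4a1 (0.70), Col4a2 (0.65) and Sparc (0.53) and the proteoglycan gene Srgn (0.79). Fibroblasts also express Col4a1, Col4a2 and Sparc, and the fibroblast list was higher on the same 2 arrays, with a median of 0.55 without the array labelled replicate 1. Trophoblast genes had a median of 0.02, a mean of -0.0061 and a test direction of down (adjusted p = 0.837), which was up without the array labelled replicate 1 (adjusted p = 0.999). In the filtered comparison the direction was down (camera, adjusted p = 0.916). Of 11 tested there, Rhox6 (1.17) and Rhox9 (0.67) rose, and the keratins Krt8 (-2.04) and Krt7 (-0.78) fell. Mesoderm and primitive streak genes had a median of -0.02 with a test direction of down (adjusted p = 0.171). In the filtered comparison 0 of 6 passed, with a median of 0.26 and a test direction of up (camera, adjusted p = 0.916). Neuroectoderm genes had a median of 0.03 with a test direction of down (adjusted p = 0.889), and Zic1 (1.23) rose of 9. Germline genes had a median of 0.04 (adjusted p = 0.654), and of 18 Dazl (1.33) and Taf7l (1.14) rose and Sycp3 fell by 1.60. Retinoid and Hox genes had a median of 0.14 (adjusted p = 0.211), and passed as higher without the array labelled replicate 1 (median 0.24, adjusted p = 0.0338; adjusted p = 0.362 with an estimated correlation). In the filtered comparison the retinoic acid hydroxylase Cyp26a1 fell by 1.72, with 0 higher of 15. Adjusted over the list alone, 10 rose and 2 fell. The rise of this list, too, stood beside the higher fibroblast genes on replicates 2 and 3. Genes of the 2-cell-like state had a median of 0.02 (adjusted p = 0.391) and 0 of 8 passed.

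The lists closest to the function of Trip12 did not pass over all 5 arrays in the main comparison. Here, too, members said to rise, fall or pass are those of the filtered comparison without the array labelled replicate 1. HECT ubiquitin ligases had a median of 0.03 (adjusted p = 0.889), and Trip12 was the only one of 21 that rose in the filtered comparison. Genes of ubiquitin fusion degradation and neddylation had a median of -0.0035, and of 0.0060 without the array labelled replicate 1 (adjusted p = 0.375 over all 5 arrays), nuclear receptor partners -0.03 (0.482) and SWI/SNF chromatin remodelling subunits -0.04 (0.072), with 0 passing of 16, 15 and 24. The SWI/SNF list passed as lower without the array labelled replicate 1 (median -0.07, adjusted p = 0.0295; adjusted p = 0.362 with an estimated correlation), and over all 5 arrays with the mean of probe sets (-0.04, 0.0313). Imprinted genes had a median of -0.03 (adjusted p = 0.406), and of 25 Mest (-0.67) and Mirg (-0.84) fell. Heat shock genes had a median of -0.02 against a mean of 0.03 (adjusted p = 0.557) and 0 of 14 passed. Genes of metallothionein and oxidative stress had a median of 0.06 (adjusted p = 0.211), and Hmox1 (0.67) rose of 16. Apoptosis regulators had a median of 0.10 (adjusted p = 0.235), and Cflar (0.93) rose of 16. Y-linked genes had a median of -0.12 (adjusted p = 0.46) and 0 of 4 passed.

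No chromosome passed as a whole. For each of the 21 chromosomes the camera adjusted p was 0.998 over all 5 arrays. The 9 measured genes of the Y chromosome had a median of -0.10, and of -0.17 without the array labelled replicate 1 (adjusted p = 0.0818). The mean of the 5 measured members of the Y-linked list was 6.93 and 6.86 in WT and 6.97 on the array labelled replicate 1. It was 6.88 on replicate 2 and 6.52 on replicate 3, so the lower mean lay on replicate 3 alone. The 50 genes that flank Trip12 on chromosome 1 had a median of -0.0034 (camera, adjusted p = 0.207, tested as a single list; 0.47 with an estimated correlation). With dim probe sets removed over all 5 arrays it was -0.05 (adjusted p = 0.0526), and with the probe set with the largest SD 0.0032 (0.281). It was -0.0233 without the array labelled replicate 1 (adjusted p = 0.055; 0.224 with an estimated correlation), and with dim probe sets also removed -0.072 (adjusted p = 0.0467 with the preset correlation, the only one run there). Of 28 flanking genes tested there 1 passed, Ap1s3, which fell by 1.42 and was named after its value was seen.

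The arrays also differed in some control probe sets. The 7 older bacterial spike-in probe sets averaged 8.33 on replicate 2, against 9.53 and 9.60 in WT, 9.54 on the array labelled replicate 1 and 9.67 on replicate 3. The 7 newer ones were level, at 9.96 on replicate 2 and between 9.89 and 9.97 on the other 4 arrays. The 3' minus 5' difference of the Gapdh control was 0.17 on replicate 2, and between 0.03 and 0.04 on the other 4 arrays. That of the Actb control was 0.71 on replicate 2 and between 0.73 and 0.79 on the others.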

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

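The alternatives that combine leaving out the array labelled Trip12 mut/mut replicate 1 with another choice were chosen after the data were examined; the others were chosen before. Normalisation, centring, filter, variance trend, array weights, a replicate block and each array left out were run for genes, probe sets and the Trip12 probe set. In each of these 0 genes and 0 probe sets passed, at 2-fold or otherwise, and Trip12 stayed higher without passing. The mean of probe sets and the probe set with the largest SD were run for genes, where 0 passed, and for lists, chromosomes and the genes that flank Trip12; an estimated correlation and fry apply only to the last 3. The difference of Trip12 was between 1.39 and 1.51 under normalisation, centring, filter, variance trend and array weights, and between 0.93 and 2.12 with 1 array left out, and 0.93 with a replicate block. With the array labelled replicate 1 left out and dim probe sets removed, 539 genes, 124 of them at least 2-fold, and 15 probe sets passed. With a variance trend and robust estimation besides, these counts were 744, 139 and 103. Without the latter 2, the flanking genes of Trip12 had a median of -0.072 and an unadjusted p of 0.0467 (camera, preset correlation). That value was not adjusted for the number of settings run. Unfiltered, they did not pass with either correlation. The cause of the difference between the gene and probe set counts was not tested. In the same filtered comparison 0 genes passed when any of the other 4 arrays was left out instead.

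Of 34 gene lists, 12 passed with the preset correlation. With an estimated correlation 0 passed, and with fry 0. Without the array labelled replicate 1, 0 passed with an estimated correlation and 14 with fry. With an estimated correlation camera has little power on so few arrays. The polycomb and DNA methylation list had an estimated correlation of -0.025, below the preset 0.01, yet its camera adjusted p went from 0.119 to 0.592. Failure there is thus weak evidence against a list. The preset may in turn be too low, as the primed epiblast list had an estimated correlation of 0.488. With the preset correlation the count was between 4 and 17 with 1 array left out: 17 without the array labelled replicate 1, 10 without replicate 2, 4 without replicate 3, and 6 and 5 without WT replicates 1 and 2. With 1 WT array left, that array is assumed to vary like the mutant arrays. The replicate numbers pair nothing that the labels describe, and only 2 are shared. Deviations of same-numbered arrays correlated at -0.05 and -0.08 across genes. With a replicate block 5 lists passed, 0 genes passed, and no other call changed. No other array shares the number of replicate 3, so the block absorbs that array. Its estimates are those without replicate 3, such as 0.93 for Trip12, and it is no separate check. No chromosome passed under any alternative. Of the named genes, lists and other Trip12 probe sets, 0 changed direction past the threshold in any setting. Counting each named gene once per setting, 2892 stayed short of the threshold and 165 passed it, the latter only without the array labelled replicate 1 and with dim probe sets removed. Counting lists likewise, 492 stayed on their side, 71 no longer passed and 13 newly passed. Signals near the background limit every statement on dim probe sets, such as the 2 dim ones of Trip12.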

Other observations

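All tests in this part were chosen, with the bounds used to judge them, after the values they concern had been seen. Because Cldn7 and Esrp1 were among the largest decreases, 29 other measured genes of epithelial junctions and epithelial splicing were tested as a list, including Cdh1 and Epcam. Over all 5 arrays their median difference was -0.43 (camera, adjusted p = 1.5e-06; adjusted p = 0.184 with an estimated correlation). Without the array labelled Trip12 mut/mut replicate 1 the median was -0.62, 22 of 29 were lower, and the adjusted p with an estimated correlation was 0.0478. With dim probe sets removed 8 of 27 fell and 0 rose. P-values of this list and of the cornified envelope list below were adjusted over these 2 lists only. They cannot be set against those adjusted over the 34 lists above. The fibroblast list, with a median of 0.55 without that array, was higher on the same 2 arrays. A lower epithelial programme on these arrays is a hypothesis only, found and tested on the same values.

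Sprr2h and Lce1f prompted the same test of 31 other cornified envelope genes. Their median difference was 0.11 over all 5 arrays (camera, adjusted p = 0.00655; adjusted p = 0.184 with an estimated correlation). Without the array labelled replicate 1 the median was 0.13, with an adjusted p of 0.303 with an estimated correlation, and 4 of 14 rose in the filtered comparison, with 0 lower. Many members of these families have near-identical sequences, so 1 transcript may be read by several probe sets.

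The array labelled Trip12 mut/mut replicate 1 lay at the WT level. An exchange with a WT array would place the other profile on a WT array. The slope across genes of the difference between the WT arrays on that between replicates 2 and 3 and this array was 0.0176 (SE 0.0027), which argues against it. A wrong label on this array alone, or WT RNA hybridised in its place, needs the array to carry none of the difference. Its slope on the difference of replicates 2 and 3 from WT was -0.0225 (SE 0.0027), against 0.774 for replicate 2 on replicate 3, each side taken against its own WT array. A mutant culture whose transcripts did not shift cannot be told apart from this, since Trip12 was at 0.983-fold on this array and no value used here shows its genotype.

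Replicates 2 and 3 differed from the other 3 arrays. The labelled split called 0 genes, so each of the 10 splits of the 5 arrays into 2 and 3 gave as many by construction, and 10 splits are too few for a share under 0.05. The highest other, 2539 genes, came from setting replicates 2 and 3 against the rest, which restates how the arrays were already seen to group. A processing batch shared by the 2 arrays has no evident reason to single out Trip12. Its brightest probe set, 4.35-fold higher without the array labelled replicate 1, ranked 10 of 11623 genes by size of difference. Of its other brighter probe sets, some were at 2.17-fold, 2.04-fold and 1.61-fold and another at 0.643-fold. The rank thus depends on the probe set and does not exclude a batch. For other genes such a batch stays open too, and cannot be told apart from genotype or from a difference between clones. Deviations of 45 spike-in probe sets on the 2 arrays correlated at -0.10, which decides nothing.

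Fibroblast genes were higher on replicates 2 and 3, and a larger share of feeder cells is a candidate explanation. Of 29 members 23, or 79.3%, lay above the WT mean on both arrays, which leaves it open for the list, while Lum and Mmp2 lay below the WT mean on replicate 2. The fall of Cnn1, which differed by -1.10 in the filtered comparison (limma, SE 0.07, adjusted p = 0.0402), is not what a larger share would give. Cnn1 was chosen after its value was seen, so it decides nothing for the list. Fewer stem cells would lower all stem cell genes alike if feeder cells do not express these genes and array signals scale alike. Neither condition was checked. The median of the pluripotency list lay 1.13 above that of the primed epiblast list. The bootstrap 95% interval, 0.45 to 1.83, resampled genes as if independent and does not measure spread between cultures. The pluripotency mean was 10.36 and 10.46 on the 2 arrays, against 10.51 and 10.53 in WT. The primed epiblast mean was 8.06 and 7.93, against 9.21 and 9.19. If those 2 conditions hold, this gap on both arrays argues against the share alone as the cause of the lower primed epiblast genes. A change in the stem cells or the feeder cells themselves was not tested.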
